A study of Homo sapiens with 15 samples.

How the data were processed

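RNA of MDA-MB-231 cells, a triple-negative human breast cancer line, was measured on 15 Affymetrix Human Genome U133 Plus arrays. Per the labels, cells were kept in medium with charcoal-stripped serum and then treated for 4, 8 or 12 h with vehicle, with 100 nM dexamethasone, with 100 nM dexamethasone and 100 nM mifepristone, or with 100 nM dexamethasone and 100 nM CORT108297. A first run of 12 arrays held all 4 treatments at all 3 times, and a second run of 3 arrays held vehicle, dexamethasone and dexamethasone with mifepristone at 4 h. The deposited values of the first run are log2 RMA values (background-corrected, quantile-normalised and summarised per probe set) made at a university genomics core, and the deposited values of the second run are log2 RMA values made with the affy package in R. The version of either software was not given in the sources used here. The sorted values showed 3 separate normalisations: the 4 h arrays of the first run had a median of 5.79, the 8 h and 12 h arrays medians from 5.56 to 5.61, and the second-run arrays medians from 6.39 to 6.40. In the second run 29.5% of probe sets had exactly the same value on all 3 arrays and 39.2% on exactly 2 of them. Vehicle and dexamethasone had the same value for 53.4% of probe sets in the second run, and, with values rounded to 2 decimals, for 24.4% at 4 h in the first run, 2.55% at 8 h and 2.08% at 12 h. For arrays the number of arrays limits the precision.

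Of 54675 probe sets, 62 control probe sets were left out. A single gene symbol was given for 41091 probe sets, several symbols for 1801 and none for 11721; the last 2 kinds were kept out of the gene tests. Each of 19775 genes was represented by its probe set with the highest mean, and the 15181 genes with a mean log2 value of at least 5 were tested. PER1 had no single-gene probe set and was not analysed here. Arrays were grouped by the treatment in their labels, and each time and run formed an array set, so that there were 4 sets. The 4 treatments were compared with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8) by a model of treatment plus array set, with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 was the threshold. The residual spread was pooled over all 15 arrays, with 8 residual and 3.11 prior degrees of freedom. The 7 arrays at 4 h were also fitted alone with the run as a block (2 residual and 1.04 prior degrees of freedom). Whether the dexamethasone effect at 8 h and 12 h differed from that at 4 h was tested by an interaction term (5 residual and 3.67 prior degrees of freedom). Single times after 4 h, and CORT108297 at 4 h, have 1 array per treatment, so only values are given for them. Each comparison adjusts over its own genes, and no adjustment was made across comparisons.

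Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, and with the estimated correlation beside it, adjusted over the 22 lists of a comparison. The lists were GR-induced targets (GR is the glucocorticoid receptor), inflammatory cytokines and NF-kB targets, AP-1 and immediate early genes, MAPK feedback regulators, circadian clock, metallothioneins, G2/M cell cycle, G1/S and DNA replication, CDK inhibitors, anti-apoptotic genes, pro-apoptotic genes, extracellular matrix and mesenchymal genes, interferon-stimulated genes, cholesterol synthesis, insulin and FOXO signalling, heat shock, ER stress and ATF4, hypoxia, steroid receptors and chaperones, luminal epithelial markers, haematopoietic markers, and fibroblast markers. Members past the threshold were counted over all genes tested and adjusted over the list alone. The share of the dexamethasone response left with an antagonist was computed per array set on genes called from the other sets, as the median signed difference from vehicle with the antagonist divided by the median signed difference with dexamethasone alone; the antagonists were compared by an exact sign-flip permutation test over sets. This share and the fold changes use the same vehicle and dexamethasone arrays in more than 1 comparison, so correlations between comparisons are given with those of simulated data without any effect.

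Named genes followed a written rule: the 12 largest changes in each direction for dexamethasone against vehicle, the 10 largest for each antagonist against dexamethasone and the 5 largest for other comparisons, all past the threshold with the same sign in every array set. The interaction has no value per array set, so the rule on signs was not applied to it. Where none passed, the 5 largest with the same sign in every set are given as values. Up to 4 members of every list with the largest dexamethasone effect, and NR3C1, FKBP5, TSC22D3, DUSP1, SGK1, GAPDH and ACTB, were also named. The comparisons, lists, naming rule and other settings tried were chosen before the data were examined; MYC, IL6 and any other gene said to be so were picked after their values were seen. The other settings were no filter or a minimum mean of 7, the mean of a gene's probe sets, quantile normalisation or cyclic loess of all arrays together, a variance prior with trend and robust moderation, a minimum of 1.5-fold, leaving out each array set or 4 h array, no block or a random block, the first run alone, all arrays with a treatment by time fit for the 4 h comparisons, a linear trend in hours, the 100 genes of smallest p, and the estimated correlation. Lists without members of the GR-induced list, list tests for the interaction, and the interaction in the first run alone were added after seeing the data. The model was tested on simulated data of the same shape with 100 changed genes per fold change: at 1.5-fold 91% were recovered for dexamethasone against vehicle, 93% for CORT108297 against dexamethasone and 49% for the interaction, and at 2-fold 100%, 98% and 87%. Changed genes were drawn at random, with the same effect on every changed array and independent noise. These shares need not hold for genes whose response varied between array sets. For CORT108297 against dexamethasone, SPINK13 (log2 -1.95 ± 0.52, SE) did not pass in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.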

Results

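Expression was measured in MDA-MB-231 cells, a human breast cancer line that lacks the oestrogen receptor and carries the glucocorticoid receptor, on 15 arrays. Vehicle, dexamethasone, and dexamethasone with mifepristone were each measured on 4 arrays, of which 2 were taken at 4 h, 1 at 8 h and 1 at 12 h. Dexamethasone with CORT108297 was measured on 3 arrays, 1 at each time. Dexamethasone is a synthetic steroid agonist of the glucocorticoid receptor, mifepristone is a steroid antagonist of that receptor and of the progesterone receptor, and CORT108297 is a compound the study used as a selective antagonist of the glucocorticoid receptor. All 3 were given at 100 nM. Each of the 15 arrays gave a log2 value for 54613 probe sets, and 15181 genes were tested. The labels do not say whether the arrays came from separate cultures, so p-values measure only the spread between these samples. The main model takes arrays from different times as repeats of a treatment. Its spread therefore also holds any change of an effect with time or run, which widens the SE of genes whose effect changes. Fold changes come from 1 model of all 15 arrays, with n given as the number of arrays of each treatment. The second run, which holds no CORT108297 array, therefore also enters the fitted values for CORT108297.

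The first comparison asked which genes respond to dexamethasone. TSC22D3, which encodes the glucocorticoid-induced leucine zipper, rose 11.1-fold (log2 3.47 ± 0.15, SE, n = 4 and 4, limma adjusted p 3.99e-07). FKBP5, a co-chaperone of the glucocorticoid receptor, rose 9.58-fold (log2 3.26 ± 0.28), and KLF9, a Krüppel-like transcription factor, rose 7.56-fold (log2 2.92 ± 0.15). IL11, a cytokine of the IL-6 family, fell 4.66-fold (log2 -2.22 ± 0.20), and SOX9, a transcription factor of progenitor cells, fell 3.50-fold (log2 -1.81 ± 0.09). Each of these 5 genes moved the same way in all 4 array sets. The other large increases were in CT75 (log2 3.50), SGPP2 (3.46), a phosphatase of sphingosine-1-phosphate, SPINK13 (3.32), FGD4 (3.21), an exchange factor for CDC42, NNMT (3.12), nicotinamide N-methyltransferase, and PDK4 (3.10), an inhibitor of pyruvate dehydrogenase. RGS2 (2.84), a brake on G protein signalling, PAPLN (2.74) and CALCR (2.71), the calcitonin receptor, completed the 12 largest. The other large decreases were in ID4 (log2 -2.08), ADAMTS1 (-1.97), SOX4 (-1.88), TENT5C (-1.85), TIMP3 (-1.76), MMP16 (-1.64), PLAU (-1.50), which encodes urokinase, the Notch target HES1 (-1.49), G0S2 (-1.46), and HBEGF (-1.42), a ligand of the EGF receptor. Some levels were under 5, the minimum mean used for testing, on vehicle arrays (CT75 and SGPP2 on 2 of 4, PAPLN on 3 of 4, CALCR on 1 of 4) or with dexamethasone (ADAMTS1 on 3 of 4), and the sizes of these fold changes are uncertain. Probe sets of a gene could also disagree: another one read 0.11 for PAPLN, -0.475 for ID4 and -0.82 for IL11. The sizes for these genes depend on the probe set. Other probe sets of FKBP5 (3.51 and 3.70), TSC22D3 (2.63) and SOX9 (-1.80) also showed large changes. The transcript of the receptor itself, NR3C1, fell by 0.42 on the log2 scale (SE 0.05, adjusted p 0.000483), and NR3C2, the mineralocorticoid receptor, fell by 1.23. GAPDH (log2 -0.04) and ACTB (0.00) did not pass the test; with cyclic loess of all arrays ACTB was at -0.003, with the opposite sign.

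**Figure D1:**
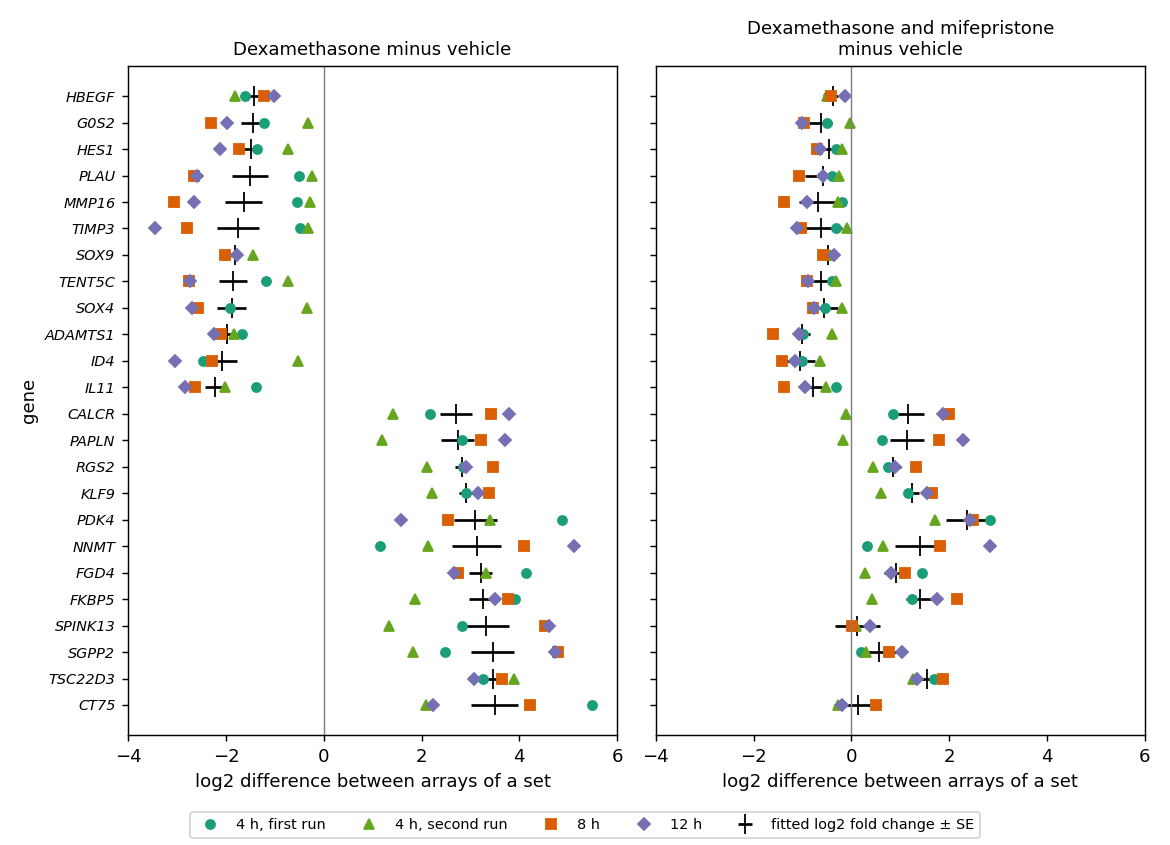
Log2 difference from vehicle (x axis) of the 12 genes that rose most and the 12 that fell most with dexamethasone (y axis), without mifepristone (left) and with it (right). Each coloured point is 1 array minus the vehicle array of its set, and black bars are the fitted value ± SE; TSC22D3 lies near 3.47 without mifepristone and near 1.54 with it.

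The fixed lists place these changes in groups. Of 29 measured GR-induced targets, 25 rose and none fell over all genes tested, and 27 rose adjusted over the list alone (camera adjusted p 9.39e-36, and adjusted p = 0.0141 with an estimated correlation). DUSP1 (log2 2.45 ± 0.20), a phosphatase of MAP kinases, and SGK1 (1.57 ± 0.15), a kinase linked to cell survival, were among them. Of 11 anti-apoptotic genes, 6 rose and 8 rose adjusted over the list alone, where 1 fell (adjusted p 2.8e-06, and adjusted p = 0.0141 with an estimated correlation). They included CFLAR (log2 1.14), an inhibitor of caspase 8, and MCL1 (0.62). Of 20 insulin and FOXO signalling genes, 8 rose, and adjusted over the list alone 9 rose and 1 fell (adjusted p 2.06e-06, and adjusted p = 0.0141 with an estimated correlation). IRS2 (log2 1.60), an adaptor of the insulin receptor, DDIT4 (1.54), an inhibitor of mTORC1, and KLF15 (1.49) rose in that list. These 3 lists, some of whose members are shared, are the calls that hold with an estimated correlation. That correlation comes from the residuals of a model without a treatment by time term. A change of effect with time or run that list members share therefore raises it. Without the members of the GR-induced list, a choice made after seeing the data, 8 anti-apoptotic genes had a camera p of 0.00142 (0.0108 with an estimated correlation) and 18 insulin and FOXO genes 2.41e-05 (0.00711). Of 7 metallothioneins, which bind zinc and copper, 6 rose by either count, led by MT1F (log2 0.93) and MT1E (0.76). The estimated correlation between these genes was 0.77, so the 6 are not independent changes. Their adjusted p was 2.56e-10, and adjusted p = 0.108 with an estimated correlation.

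The lists below 0 included growth and immune genes. Of 30 G1/S and DNA replication genes, 1 rose and 6 fell, and adjusted over the list alone 1 rose and 27 fell (adjusted p 3.13e-10, and adjusted p = 0.312 with an estimated correlation). Over all genes tested, 1 rose and 26 fell when the second run was left out. CDC6, which licenses replication origins, fell by 0.59 on the log2 scale (adjusted p 0.0466). None of 28 G2/M genes passed limma's test by either count, and the list was lower at the preset correlation (adjusted p 4.85e-06, and adjusted p = 0.534 with an estimated correlation). In that list 4 genes fell when the second run was left out. Of 25 interferon-stimulated genes, 4 fell and 11 fell adjusted over the list alone, among them IFIT2 (log2 -0.64) and RIGI (-0.59), a sensor of viral RNA. The adjusted p was 1.23e-05, and adjusted p = 0.374 with an estimated correlation, and without the second run 8 fell. Of 24 inflammatory genes, 1 rose and 5 fell, against 1 and 8 adjusted over the list alone (adjusted p 0.00602, and adjusted p = 0.148 with an estimated correlation), with IRF1, an interferon regulatory factor, at log2 -0.70 and CCL20, a chemokine, at 1.02. CCL20 was under 5 on 3 of 4 vehicle arrays, so the size of its change is uncertain. Without the second run that list had 3 higher and 5 lower and an adjusted p of 0.313. Of 13 luminal markers, 3 fell, and adjusted over the list alone 1 rose and 7 fell (adjusted p 0.00599, and adjusted p = 0.31 with an estimated correlation), with the tight-junction gene CLDN4 at log2 -1.23.

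The other 13 lists did not pass for dexamethasone. Of 21 AP-1 and immediate early genes, 1 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p 0.0695), with JUN at log2 -1.16 and IER3 at -1.41; without the second run 4 rose and 6 fell. Of 18 hypoxia genes, 2 rose and 3 fell (2 and 6 over the list alone, adjusted p 0.0583), with ANGPTL4, a secreted inhibitor of lipoprotein lipase, at 2.61 and VEGFA at -0.60. MAPK feedback regulators had 3 higher and 3 lower of 18 (3 and 5 over the list alone, adjusted p 0.697) and differed in sign between their median (log2 -0.10) and mean (0.11), with a test direction of down. The clock list had 3 higher and 2 lower of 17 (3 and 4, adjusted p 0.818), with NFIL3 at 0.71 and BHLHE41 at -0.57. CDK inhibitors had 1 higher and 1 lower of 5 (2 and 2, adjusted p 0.97), namely CDKN1C (log2 1.08) and CDKN1B (-0.33). Extracellular matrix genes had 6 higher and 1 lower of 30 (6 and 8, adjusted p 0.97), with the integrin ITGA5 at 1.15 and the laminin chain LAMB3 at -0.60; their median was -0.02 and their mean 0.03. Of these genes 6 were higher and 6 lower without the second run. Steroid receptors and chaperones had 1 higher and 2 lower of 14 by either count (adjusted p 0.516; 1 and 3 without the second run), with a median of -0.04 and a mean of 0.09. ER stress genes had 3 lower of 17 (1 higher and 3 lower over the list alone, adjusted p 0.516), among them SLC7A11 (log2 -0.57), and pro-apoptotic genes 1 lower of 15 by either count (adjusted p 0.417), the death receptor gene TNFRSF10B at -0.27. No member passed limma's test, by either count, in cholesterol synthesis (14 genes, adjusted p 0.516), heat shock (10 genes, adjusted p 0.818), haematopoietic markers (7 genes, adjusted p 0.97) or fibroblast markers (7 genes, adjusted p 0.891), though 1 cholesterol synthesis gene was lower without the second run. Haematopoietic markers had a median of -0.03, a mean of 0.00 and a test direction of up.

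**Figure D2:**
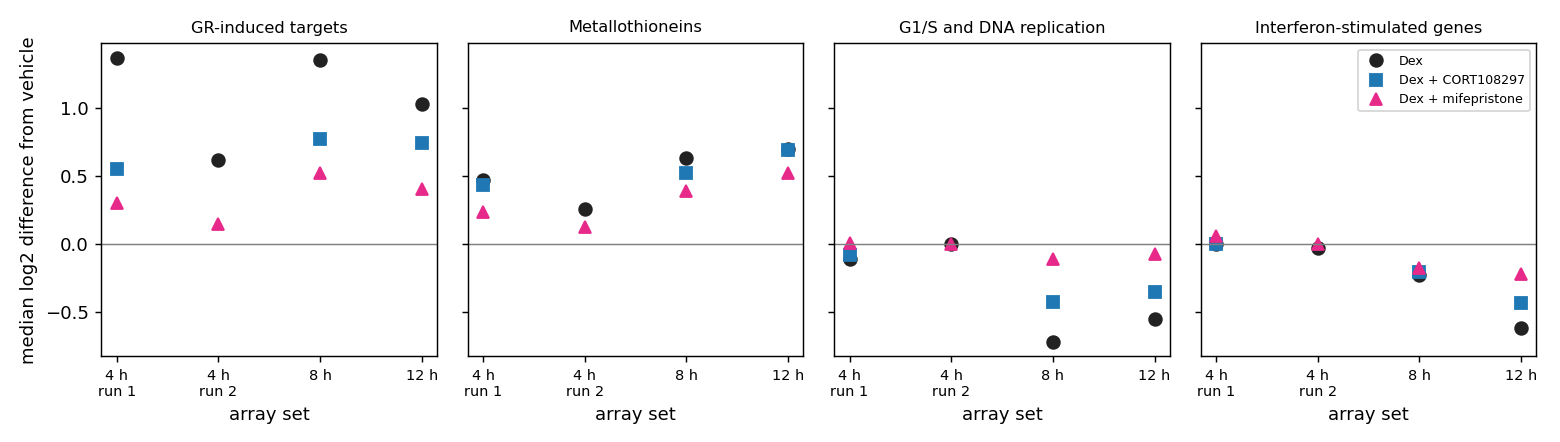
Median log2 difference from vehicle (y axis) of 4 gene lists in each array set (x axis), with dexamethasone alone (circles), with CORT108297 (squares) and with mifepristone (triangles); each point is a median over genes of single arrays, without error. With dexamethasone the GR-induced list stood at 1.37 at 4 h in the first run, 0.62 at 4 h in the second run, 1.35 at 8 h and 1.03 at 12 h, and the G1/S list at -0.73 at 8 h and -0.56 at 12 h.

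In all, 1093 of 15181 genes passed for dexamethasone against vehicle, 528 higher and 565 lower, and 3772 had an unadjusted p under 0.05 where chance gives 759. The number of called genes depended on each array set. It was 526 without the 4 h arrays of the first run, 248 without 8 h, 356 without 12 h and 1989 without the second run, and 60 without array-set blocks. Of the 24 genes with the largest changes, 9 no longer passed without the 8 h arrays (CT75, NNMT, ID4, SOX4, TENT5C, TIMP3, MMP16, PLAU and G0S2, adjusted p from 0.0593 to 0.409). Of these, SOX4, TENT5C, TIMP3, MMP16, PLAU and G0S2 also did not pass without 12 h (0.0574 to 0.286). PLAU did not pass without the 4 h arrays of the first run (0.0576).

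Adding mifepristone to dexamethasone asked how much of that response the antagonist removes. Genes that dexamethasone raised were lower with mifepristone: TSC22D3 fell 3.81-fold against dexamethasone alone (log2 -1.93 ± 0.15, SE, n = 4 and 4, limma adjusted p 0.000104), FKBP5 3.64-fold (-1.86 ± 0.28) and CT75 10.3-fold (-3.37 ± 0.48). With mifepristone CT75 was under 5 on 2 of 4 arrays and SGPP2 on 1 of 4, so the sizes of their fold changes are uncertain. Genes that dexamethasone lowered were higher: IL11 rose 2.69-fold (log2 1.43 ± 0.20), SOX9 2.50-fold (1.32 ± 0.09) and SOX4 2.49-fold (1.31 ± 0.29). Another probe set of IL11 read 0.47, and the other one of SOX9 read 1.38. SPINK13 (-3.20), SGPP2 (-2.89), FGD4 (-2.31), RGCC (-2.04), the VEGF receptor KDR (-2.00), RGS2 (-1.98) and PXYLP1 (-1.92) made up the rest of the 10 largest decreases, and TENT5C (1.23), PRAG1 (1.10), IER3 (1.09), GEM (1.08), HBEGF (1.04), HES1 (1.03) and CLDN4 (1.00) the rest of the 10 largest increases. NR3C1 rose by 0.34 (SE 0.05). DUSP1 fell by 1.25 and SGK1 fell by 1.09. ANGPTL4 (log2 -0.32, adjusted p 0.178), PDK4 (-0.74, adjusted p 0.36) and PLIN2 (0.03, adjusted p 0.903), a coat protein of lipid droplets, did not pass, and neither did GAPDH (0.03) or ACTB (0.03).

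Against dexamethasone alone, 17 of 29 GR-induced targets fell with mifepristone and none rose, and 24 fell adjusted over the list alone (camera adjusted p 6.62e-25, and adjusted p = 0.0268 with an estimated correlation). In insulin and FOXO signalling 8 of 20 fell (9 over the list alone, adjusted p 2.02e-07, and adjusted p = 0.0245 with an estimated correlation), with IRS2 at log2 -0.74. Among anti-apoptotic genes 4 of 11 fell (6 over the list alone, adjusted p 8e-05, and adjusted p = 0.0274 with an estimated correlation), with CFLAR at -0.72. The G1/S list was higher, with 2 of 30 genes past the threshold and 23 adjusted over the list alone (adjusted p 4.04e-10, and adjusted p = 0.353 with an estimated correlation). Metallothioneins were lower (2 of 7, and 6 over the list alone, adjusted p 8e-05, and adjusted p = 0.353 with an estimated correlation). G2/M genes (adjusted p 0.000125, and adjusted p = 0.673 with an estimated correlation) and interferon-stimulated genes (adjusted p 0.000843, and adjusted p = 0.634 with an estimated correlation) were higher as lists, though no G2/M gene passed limma's test and the 1 interferon-stimulated gene that passed was lower. Inflammatory genes had 3 higher of 24 (4 higher and 1 lower over the list alone, adjusted p 0.00755, and adjusted p = 0.194 with an estimated correlation) and AP-1 genes 4 higher of 21 (8 higher and 3 lower over the list alone, adjusted p 0.0121, and adjusted p = 0.353 with an estimated correlation). Without the second run the inflammatory and AP-1 lists had adjusted p values of 0.126 and 0.135, 4 G1/S genes were higher, 2 inflammatory genes were higher and no interferon-stimulated gene passed.

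In all, 360 genes passed for mifepristone added to dexamethasone, 103 higher and 257 lower, and 2911 had an unadjusted p under 0.05. Of the 257 lower genes, 226 were among the 528 that dexamethasone raised (8.94 if the calls were independent), and of the 103 higher genes, 93 were among the 565 that it lowered (3.83 if independent). No gene passed in the same direction in both. The comparisons share the dexamethasone arrays, which alone gives a relation in this direction, though a weaker one in simulated data. Across genes, which are not independent replicates, the effects had r = -0.90 and a covariance of -0.0383, against -0.50 and -0.0033 in simulated data without effects. With separate dexamethasone arrays for each comparison, r ranged from -0.80 to -0.46 over 6 splits. The count was 103 without the 4 h arrays of the first run, 70 without 8 h, 114 without 12 h and 544 without the second run, and 2 without array-set blocks. Of the 20 genes with the largest changes, 10 no longer passed without the 8 h arrays (IL11, SOX4, TENT5C, HES1, CLDN4, CT75, SPINK13, SGPP2, KDR and FKBP5, adjusted p from 0.0566 to 0.392). The same genes except CT75 did not pass without 12 h (0.0563 to 0.304). Of the 10, 7, all but IL11, CT75 and SGPP2, did not pass without the 4 h arrays of the first run (0.0598 to 0.203).

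The same question was asked of CORT108297 added to dexamethasone. SPINK13 had the largest difference (log2 -1.95, 95% interval -3.09 to -0.81, n = 3 and 4), followed by CT75 (-1.16, -2.32 to 0.01), IGFBP3, a binding protein of insulin-like growth factors (-1.08, -1.58 to -0.59), SGPP2 (-1.06, -2.12 to 0.01) and TRNP1 (-0.99, -1.49 to -0.48). The fitted difference was -0.48 (-0.84 to -0.12) for TSC22D3 and -0.38 (-1.07 to 0.31) for FKBP5. The sets that hold both treatments gave -0.30, -0.48 and -0.28 for TSC22D3 and -0.77, -0.44 and -0.53 for FKBP5 at 4, 8 and 12 h, and so ranked them the other way at 4 h and 12 h. SPINK13 stood at -2.02, -2.67 and -2.48 in these sets. SOX9 (log2 0.70) and IRF2BPL (0.44), picked after their values were seen, had the smallest adjusted p, 0.0669. GR-induced targets had no member past the threshold over all genes tested and 4 lower adjusted over the list alone (camera adjusted p 4.65e-12, and adjusted p = 0.184 with an estimated correlation). Insulin and FOXO signalling was lower as a list (3 over the list alone, adjusted p 0.00264, and adjusted p = 0.184 with an estimated correlation), as were cholesterol synthesis (0 over the list alone, adjusted p 0.00264, and adjusted p = 0.548 with an estimated correlation) and anti-apoptotic genes (0 over the list alone, adjusted p 0.0269, and adjusted p = 0.252 with an estimated correlation). The G1/S list was higher (adjusted p 4.7e-05, and adjusted p = 0.612 with an estimated correlation), as was G2/M (adjusted p 0.019, and adjusted p = 0.805 with an estimated correlation), each with 0 genes over the list alone. Inflammatory genes (1 higher over the list alone, adjusted p 0.019, and adjusted p = 0.252 with an estimated correlation) and AP-1 genes (3 higher over the list alone, adjusted p 0.0415, and adjusted p = 0.548 with an estimated correlation) were also higher, and without the second run both had an adjusted p of 0.23.

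No gene passed limma's test for CORT108297 added to dexamethasone, and 812 had an unadjusted p under 0.05 where chance gives 759. Without the second run, which holds no array with CORT108297, 5 genes passed: SOX4 (log2 1.06), SOX9 (0.78) and HAS2 (0.65), a hyaluronan synthase, were higher, and ZDHHC8BP (-0.64) and TP53I3 (-0.56) were lower; HAS2, ZDHHC8BP and TP53I3 were named after their values were seen. The effect sizes of dexamethasone and of added CORT108297 had r = -0.72 across genes and a covariance of -0.0173, against -0.45 and -0.0033 in simulated data without effects, and r from -0.61 to -0.34 with separate dexamethasone arrays. The effects of the 2 antagonists against dexamethasone had r = 0.80 and a covariance of 0.0143, against 0.45 and 0.00331 in simulated data, and r from 0.34 to 0.60 with separate dexamethasone arrays.

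The antagonists were compared directly at the same dose and times. RGS2 was lower with mifepristone than with CORT108297 by 2.90-fold (log2 -1.54 ± 0.18, SE, n = 4 and 3, limma adjusted p 0.0211), TSC22D3 by 2.73-fold (-1.45 ± 0.16) and KLF9 by 2.59-fold (-1.37 ± 0.17). ARRDC2 (-0.60), IRS2 (-0.52) and ZMYND8 (-0.32), the last outside the naming rule and picked after its value was seen, were also lower, and IRF1 was higher (0.44 ± 0.06). FKBP5 did not pass (log2 -1.49, 95% interval -2.18 to -0.80, adjusted p 0.183), and neither did SOX9 (0.62, 0.41 to 0.83, adjusted p 0.0646). ANGPTL4 (-0.13, interval -0.40 to 0.14) and PLIN2 (0.19, interval -0.04 to 0.43) did not differ detectably between the antagonists. Of 29 GR-induced targets 3 were lower with mifepristone and 14 adjusted over the list alone (camera adjusted p 4.24e-22, and adjusted p = 0.0371 with an estimated correlation). Insulin and FOXO genes (1 of 20 lower, 6 over the list alone, adjusted p 2.6e-07, and adjusted p = 0.0238 with an estimated correlation) and anti-apoptotic genes (0 of 11, 2 lower over the list alone, adjusted p 0.000218, and adjusted p = 0.0371 with an estimated correlation) were also lower. In all 7 genes passed, 1 higher and 6 lower, and 902 had an unadjusted p under 0.05. G1/S genes (adjusted p 2.99e-06, and adjusted p = 0.576 with an estimated correlation), cholesterol synthesis (0.000282, and adjusted p = 0.439 with an estimated correlation), interferon-stimulated genes (0.00345, and adjusted p = 0.652 with an estimated correlation), and G2/M genes (0.012, and adjusted p = 0.789 with an estimated correlation) were higher as lists. So were AP-1 genes (0.0143, and adjusted p = 0.397 with an estimated correlation). Metallothioneins were lower (6 of 7 over the list alone, adjusted p 4.09e-06, and adjusted p = 0.349 with an estimated correlation). Without the second run the AP-1 list had an adjusted p of 0.0616. No gene passed limma's test when the 4 h arrays of the first run, the 8 h or the 12 h arrays were left out, and the adjusted p of the 6 genes of the naming rule then ranged from 0.234 to 0.609. None passed without array-set blocks, 11 passed without the second run, and 1 with quantile normalisation of all arrays.

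The response that remained was measured against vehicle. With dexamethasone and mifepristone, ANGPTL4 was still 4.91-fold above vehicle (log2 2.30 ± 0.11, SE, n = 4 and 4, limma adjusted p 4.92e-06), TSC22D3 2.91-fold (1.54 ± 0.15), KLF9 2.35-fold (1.23 ± 0.15), IRS2 1.81-fold (0.85 ± 0.06) and PLIN2 1.71-fold (0.77 ± 0.10). IRF2BPL was lower (log2 -0.35 ± 0.05). PDK4 (log2 2.36, adjusted p 0.0938) and FKBP5 (1.40, adjusted p 0.138) did not pass. Of GR-induced targets, 3 of 29 were higher, and 20 adjusted over the list alone (camera adjusted p 9.34e-27, and adjusted p = 0.0432 with an estimated correlation), the only list of the 22 to hold with an estimated correlation here. None of 7 metallothioneins passed over all genes and 7 did adjusted over the list alone (adjusted p 4.43e-13, and adjusted p = 0.0809 with an estimated correlation). Hypoxia genes differed in sign between their median (log2 -0.09) and mean (0.02), with a test direction of down (adjusted p 0.0274, and adjusted p = 0.25 with an estimated correlation). Anti-apoptotic genes were higher (4 of 11 over the list alone, adjusted p 0.000608, and adjusted p = 0.0655 with an estimated correlation), and interferon-stimulated genes (adjusted p 0.0295, and adjusted p = 0.75 with an estimated correlation) and luminal markers (adjusted p 0.0295, and adjusted p = 0.47 with an estimated correlation) were lower. In all 11 genes passed, 10 higher and 1 lower, and 1210 had an unadjusted p under 0.05. Over all genes tested, 7 GR-induced targets and 3 metallothioneins were higher without the second run. The count of all genes was 3 without the 4 h arrays of the first run, 2 without 8 h, 2 without 12 h, 42 without the second run and 1 without array-set blocks. Of the 6 genes of the naming rule, TSC22D3, KLF9, PLIN2 and IRF2BPL did not pass without the 4 h arrays of the first run (adjusted p from 0.0676 to 0.166), without 8 h (0.263 to 0.59) or without 12 h (0.0882 to 0.391), and IRF2BPL also did not pass without the second run (0.0935).

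With dexamethasone and CORT108297, TSC22D3 was 7.94-fold above vehicle (log2 2.99 ± 0.16, SE, n = 3 and 4, limma adjusted p 5.77e-06), FKBP5 7.38-fold (2.88 ± 0.31) and KLF9 6.10-fold (2.61 ± 0.17). These fitted values also draw on the second run, which holds no CORT108297 array. At 4, 8 and 12 h in the first run FKBP5 read 12.26, 13.19 and 12.9 with CORT108297. With vehicle it read 9.12, 9.86 and 9.93, so its fitted value lay below the difference in each set. Those of TSC22D3 and KLF9 lay within the range of their sets. ADAMTS1, a secreted metalloprotease, was 3.78-fold lower (log2 -1.92 ± 0.18), and SOX9 2.15-fold lower (-1.11 ± 0.10). The level of ADAMTS1 with CORT108297 was under 5 on 3 of 3 arrays, so the size of its fold change is uncertain. NNMT (2.77), PAPLN (2.43, with vehicle under 5 on 3 of 4 arrays), ID4 (-1.85), IL11 (-1.44) and the lipase gene LIPG (-1.15) were the others of the 5 largest in each direction. For PAPLN, ID4 and IL11 another probe set changed much less with dexamethasone alone, so these sizes depend on the probe set. Of 29 GR-induced targets, 19 were higher, and 24 adjusted over the list alone (camera adjusted p 6.89e-38, and adjusted p = 0.0144 with an estimated correlation). Anti-apoptotic genes (4 of 11, 6 over the list alone, adjusted p 2.39e-06, and adjusted p = 0.0148 with an estimated correlation) and insulin and FOXO genes (5 of 20 by either count, adjusted p 1.03e-05, and adjusted p = 0.0217 with an estimated correlation) were higher, and so were metallothioneins (6 of 7 by either count, adjusted p 1.04e-13, and adjusted p = 0.0538 with an estimated correlation). In all 228 genes passed, 154 higher and 74 lower, and 1995 had an unadjusted p under 0.05. Of the 154, 150 were also raised by dexamethasone alone (5.36 if independent), and of the 74, 73 were also lowered (2.75 if independent). Both comparisons use the same vehicle arrays, which alone gives a relation in this direction, though a weaker one in simulated data. Across genes the effects had r = 0.92 and a covariance of 0.0398, against 0.45 and 0.00331 in simulated data without effects, and r from 0.60 to 0.83 with separate vehicle arrays. The count was 76 without the 4 h arrays of the first run, 35 without 8 h, 45 without 12 h, 404 without the second run and 15 without array-set blocks. FKBP5, NNMT, PAPLN, ID4, IL11 and LIPG did not pass without the 8 h (adjusted p from 0.0662 to 0.547) or the 12 h arrays (0.0575 to 0.315), and PAPLN and ID4 did not pass without the 4 h arrays of the first run (0.107 and 0.153). G1/S genes (adjusted p 2.39e-06, and adjusted p = 0.478 with an estimated correlation), interferon-stimulated genes (4.67e-05, and adjusted p = 0.478 with an estimated correlation), and G2/M genes (0.000894, and adjusted p = 0.623 with an estimated correlation) were lower as lists. Luminal markers (0.00433, and adjusted p = 0.296 with an estimated correlation) and hypoxia genes (0.0497, and adjusted p = 0.296 with an estimated correlation) were also lower. Without the second run the hypoxia list had an adjusted p of 0.0612. Beyond the comparison of dexamethasone with vehicle, median, mean and test differed in sign only in lists that did not pass, apart from the hypoxia list given above. These were MAPK feedback, CDK inhibitors, extracellular matrix, heat shock and steroid receptors for mifepristone against dexamethasone, and CDK inhibitors and steroid receptors for CORT108297 against dexamethasone. They were CDK inhibitors, clock, ER stress, steroid receptors and haematopoietic markers between the antagonists. Against vehicle they were AP-1, MAPK feedback, pro-apoptotic, insulin and FOXO, and steroid receptors with mifepristone, and MAPK feedback, CDK inhibitors, extracellular matrix, ER stress and steroid receptors with CORT108297.

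On genes called from the other array sets, CORT108297 left 70.6% ± 2.57 (SD, n = 3 sets) of the dexamethasone response and mifepristone left 40.9% ± 12.1 (SD, n = 4 sets). The 3 first-run sets gave 28.3%, 36.5% and 42.2% with mifepristone at 4, 8 and 12 h, a mean of 35.6% ± 7.00. The second run gave 56.9%, from a median dexamethasone effect of only 0.04 on the log2 scale, and it was 0% for raised and 230% for lowered genes taken apart. The antagonists differed by 34.9 ± 4.69 percentage points, with CORT108297 above mifepristone in 3 of 3 sets (exact sign-flip permutation test, two-sided p = 0.25, the smallest p that 3 sets allow). Single genes kept very different shares of their mean dexamethasone difference over the 3 first-run sets, which hold both antagonists. With mifepristone SPINK13 kept 3.35%, against 40.0% with CORT108297. TSC22D3 kept 49.2% with mifepristone and 89.4% with CORT108297, and FKBP5 46.2% and 84.4%. ANGPTL4 kept 89.0% and 91.4%.

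**Figure D3:**
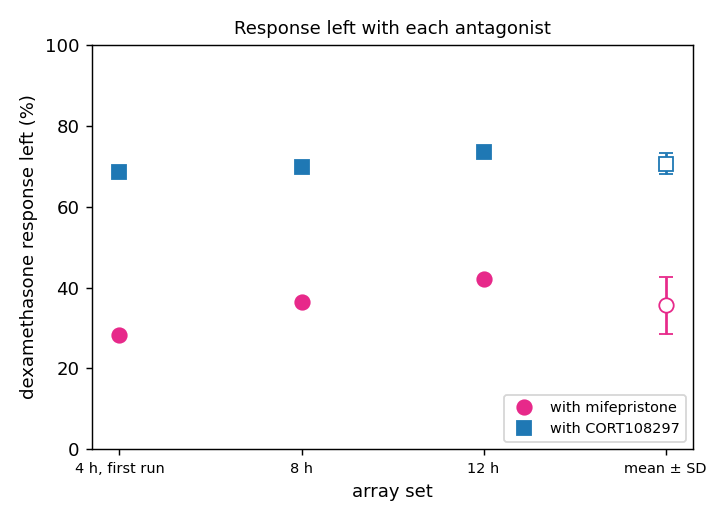
Share of the dexamethasone response left (y axis, percent) at 4, 8 and 12 h in the first run (x axis) with mifepristone (circles) and with CORT108297 (squares); open symbols are means ± SD over the 3 sets. CORT108297 lay at 68.5%, 69.8% and 73.4%, above mifepristone in 3 of 3 sets.

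At 4 h, the time with 2 arrays per group, the largest dexamethasone differences of the same sign in both runs were in PDK4 (log2 4.14 ± 0.44, SE, n = 2 and 2, limma adjusted p 0.246), CT75 (3.78 ± 1.02), FGD4 (3.73 ± 0.34), TSC22D3 (3.57 ± 0.32) and FKBP5 (2.89 ± 0.59). With mifepristone added, the largest were in CT75 (-3.67 ± 1.02), FGD4 (-2.87 ± 0.34), PXYLP1 (-2.46 ± 0.24), TSC22D3 (-2.10 ± 0.32) and FKBP5 (-2.05 ± 0.59). No gene passed limma's test for dexamethasone at 4 h (1118 with an unadjusted p under 0.05, smallest adjusted p 0.104) or for added mifepristone (1421, smallest adjusted p 0.309). The first count became 38 after cyclic loess and 5 after quantile normalisation of all arrays.

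The last comparison asked whether the dexamethasone effect at 8 h and 12 h differed from that at 4 h. NNMT was raised more later (difference of log2 effects 2.96 ± 0.40, SE, limma adjusted p 0.00304): its effect was 1.16 and 2.13 in the 2 sets at 4 h, 4.09 at 8 h and 5.12 at 12 h. TIMP3, an inhibitor of metalloproteases, was lowered more later (-2.72 ± 0.19), as were MMP16 (-2.44) and PLAU (-2.25). SLCO4A1 (-2.22) was at 0.16 and 0 at 4 h and at -1.47 and -2.81 later. SGPP2 (2.59), SPINK13 (2.48), NEBL (2.2) and DNER (2.03) were raised more later, while PDK4 was raised less (-2.07 ± 0.46). MYC and IL6, picked after their values were seen, also differed. MYC stood at 0.17 and 0.05 at 4 h and at 1.57 and 1.62 later. IL6 stood at -1.29 and -2.13 at 4 h and at 0.21 and 0.32 later. In the first run its level at 4, 8 and 12 h was 8.71, 6.7 and 6.64 with vehicle. With dexamethasone it was 7.42, 6.91 and 6.96, so its vehicle level differed more between times. For NNMT these levels were 8.35, 6.66 and 6.08 with vehicle and 9.51, 10.75 and 11.2 with dexamethasone. MYC read 11.33, 10.43 and 10.27 with vehicle and 11.5, 12 and 11.89 with dexamethasone, so its vehicle level also differed more between times. The 4 h arrays were normalised apart from the later ones, which limits a comparison of levels across times. G1/S genes were lower later as a list (1 higher and 22 lower of 30, 2 and 26 adjusted over the list alone, camera adjusted p 2.47e-13, and adjusted p = 0.325 with an estimated correlation), and so were interferon-stimulated genes (1 higher and 11 lower of 25, 1 and 13 over the list alone, adjusted p 1.05e-06, and adjusted p = 0.355 with an estimated correlation). In all 1933 genes passed, 786 with a higher and 1147 with a lower effect later, and 4005 had an unadjusted p under 0.05. Without the 12 h arrays no gene passed limma's test (smallest adjusted p 0.0524, 4237 with an unadjusted p under 0.05). The count was 2514 without 8 h, 620 without the 4 h arrays of the first run and 520 without the second run. The 10 genes of the naming rule all lost their call without 12 h (adjusted p from 0.0524 to 0.302), SPINK13 and PDK4 also without 8 h (0.159 and 0.126), and PDK4 without the 4 h arrays of the first run (0.0821). Time and array set cannot be told apart for the 8 h and 12 h effects, each of which rests on 1 array per treatment.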

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

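The test of equal numbers of arrays was chosen only after its result was seen, the slopes below were defined after the numbers they were to meet had been written and their intervals were set against 0.8 after they were seen, and the splits and the tests on the time pattern were chosen before, except that the counts without the 2 sets at 4 h were set side by side after they were seen. Of all 35 splits of the same 8 or 7 arrays, only the real one reached 360 genes for mifepristone against dexamethasone (highest other split 0, 1 of 35 splits as large). The same held for the 7 genes of mifepristone against CORT108297 (highest other 1, 1 of 35). Both shares were under 0.05. Arrays were blocked by array set and only 8 of the 35 splits part as many sets, so this count cannot exclude chance for either. Between the antagonists limma called 0 genes when any 1 first-run set was left out. The count of all 35 did not exclude chance for dexamethasone against vehicle (1093, highest other 2826, 2 of 35), dexamethasone with mifepristone against vehicle (11, highest other 1170, 2 of 35) or dexamethasone with CORT108297 against vehicle (228, highest other 313, 2 of 35). For CORT108297 against dexamethasone the count says nothing, since any split has at least the 0 genes of the real one (35 of 35, highest other 313). The splits with many genes follow a structure of the samples. The one with 2826 genes leaves both 4 h sets whole and parts the sets at 8 h and 12 h as the treatments do, and the one with 1170 parts all 4 h arrays from all later ones. One with 313 is the real grouping with the second-run vehicle array moved, which has no CORT108297 array in its set, and the other with 313 puts both 12 h arrays apart from all 4 h arrays and parts the 8 h set by treatment. The 8 splits that part as many array sets are too few for a share under 0.05; among them the highest other split had 0 genes for dexamethasone against vehicle, for mifepristone against dexamethasone, between the antagonists, and for dexamethasone with mifepristone against vehicle. It had 313 for dexamethasone with CORT108297 against vehicle and 11 for CORT108297 against dexamethasone.

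A difference between times drew attention first: the dexamethasone effect of 1933 genes differed between 4 h and later. For the genes of the naming rule the differences were 2.96 for NNMT, 2.59 for SGPP2, 2.48 for SPINK13, 2.2 for NEBL, 2.03 for DNER, -2.72 for TIMP3, -2.44 for MMP16, -2.25 for PLAU, -2.22 for SLCO4A1 and -2.07 for PDK4 on the log2 scale.

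Of the technical explanations of this time pattern, compression met its test, which cannot tell it from a response that grows with time. Compression of differences at 4 h by the separate RMA of small array sets would make effects smaller at 4 h. A larger absolute effect later was seen in 96.12% of the 1933 genes, which a growing response would give as well. The other 75 had the larger effect at 4 h, 10 of them at least 2-fold there with the same sign. The GR-induced list had a median dexamethasone effect of 1.37 at 4 h in the first run and 0.62 in the second. It was 1.35 at 8 h and 1.03 at 12 h, so within the first run it was not smaller at 4 h. Compression alone does not turn a sign, and 725 of the 1933 genes had opposite signs at 4 h and later, of which 498 had a mean absolute effect under 0.1 at 4 h and 12 were at least 1.5-fold there. Without the second run 520 genes passed, 488 of them among the 1933, so these do not need it. Its share in the rest is undecided, since 620 passed without the 4 h arrays of the first run and the loss of either 4 h set lowers the count; 0 passed without the 12 h arrays and 2514 without 8 h. A response that grows with time, the biological explanation in the design, stays open, as time and normalisation change together.

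The dexamethasone effect in the second run was smaller than in the first at 4 h, with a slope of 0.612 over genes called from 8 h and 12 h. If exact ties between its 3 arrays were the cause, genes without ties should have a slope of at least 0.8, and theirs was 0.657 (95% interval 0.602 to 0.72); a least-squares slope gave 0.586 (0.537 to 0.636). If loss of differences in dim probe sets were the cause, bright genes should be free of it, and theirs was 0.727 (0.625 to 0.83), or 0.651 (0.567 to 0.747) by least squares. All slopes of the genes without ties lay under 0.7 and all their intervals below 0.8. These intervals come from resampling genes, which are not independent replicates. Each run has a single array per treatment at 4 h, so the intervals hold no error between arrays. The slopes therefore cannot decide whether ties are the whole cause. The intervals of the bright genes reached 0.83 and, for genes called from all arrays, 0.856, so dim probe sets stay open as well. No biological explanation was tested for a repeat of the same treatment. The vehicle arrays at 4 h also stood far apart in some genes. The first-run array read 8.71 for IL6, 4.56 for CCL20 and 8.72 for ID4, with a median of 5.79 over probe sets. The second-run array read 12.6, 10.9 and 5.89, with a median of 6.39. Whether the cells differed between the runs was not tested.

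Fewer genes passed for CORT108297 than for mifepristone against dexamethasone. Fewer arrays with CORT108297 cannot be the whole cause, since with 3 arrays of each treatment 544 genes passed for mifepristone and 5 for CORT108297. With 3 arrays of each, a weaker effect of this dose of CORT108297 on the same genes remains a hypothesis, suggested by the same data, and whether another dose would differ was not tested.

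A signal also appeared outside the genes tested: 46 of 1349 probe sets with several gene symbols passed for dexamethasone against vehicle, 25 higher and 21 lower. Of 4842 probe sets with no gene named, 152 passed, 96 higher and 56 lower.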

How the results depend on the processing

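The interaction with the first run alone was added after the result was seen; the other alternatives were planned. No gene named for its large change reversed: of 1232 values for 91 such genes and comparisons, 1067 kept their direction and side of the threshold and 165 kept the direction but no longer passed. Outside the interaction these genes were named for having the same sign in every array set. Leaving out sets or arrays could therefore hardly turn a direction, and the lack of reversals there says little. ACTB, which did not pass, was outside this count and turned to -0.003 for dexamethasone with cyclic loess. Of the main counts and shares, 81 values stayed close and 64 moved. A count was close if it and the main count were within 1.5-fold of each other or both 0. A share was close if it differed from the main share by less than the SD over array sets. With a minimum mean of 7, 4 genes passed for CORT108297 against dexamethasone, 12 for mifepristone against CORT108297 and 1 for dexamethasone at 4 h; the mean of a gene's probe sets gave 2 for CORT108297 against dexamethasone. Quantile normalisation gave 1 for mifepristone against CORT108297, 17 for dexamethasone with mifepristone against vehicle and 5 for dexamethasone at 4 h, where cyclic loess gave 38. Trend and robust moderation gave 4 for CORT108297 against dexamethasone, 17 for mifepristone against CORT108297, 20 for dexamethasone with mifepristone against vehicle and 1 for dexamethasone at 4 h. A minimum of 1.5-fold, which can only lower a count, left 352 for dexamethasone, 142 for added mifepristone, 4 between antagonists, 7 and 122 for mifepristone and CORT108297 against vehicle, and 791 for later against 4 h. Leaving out 1 array set gave 248 to 1989 for dexamethasone, 70 to 544 for added mifepristone, 0 to 5 for added CORT108297, 0 to 11 between antagonists, 2 to 42 and 35 to 404 for mifepristone and CORT108297 against vehicle, and 0 to 2514 for later against 4 h. Each upper end but the last came without the second run, the same as the first run alone: 1989, 544, 5, 11, 42 and 404 in that order, and 520 for later against 4 h. Without array-set blocks (treatment and time alone) the counts were 60, 2, 0, 0, 1 and 15, since differences between normalisations then enter the spread, and the median of all genes moved to -0.13 for CORT108297 against dexamethasone, 0.14 between antagonists and -0.13 for CORT108297 against vehicle. A random block gave 3 for added CORT108297, 36 between antagonists and 44 for dexamethasone with mifepristone against vehicle. With an estimated correlation 3 of 9 lists held for dexamethasone, 3 of 9 for added mifepristone, 0 of 8 for added CORT108297, 3 of 9 between antagonists, 1 of 6 for mifepristone and 3 of 9 for CORT108297 against vehicle. The share left with CORT108297 was 66.7% on the 100 genes of smallest p. Except where the construction is named, the cause was not tested. For 16 pairs of list and comparison the list median, at most 0.02 from 0, changed sign under a scaling. Genes with a mean under 5 were not tested, and equal values on second-run arrays limit what small differences near background can show.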

Other observations

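The tests on PPAR targets and on lists for the interaction with time were chosen only after the result was seen. ANGPTL4, PLIN2 and PDK4, known targets of the PPAR receptors that sense fatty acids, were picked after their values were seen. ANGPTL4 and PDK4 are also members of the GR-induced list. Over the 3 first-run sets ANGPTL4 kept 89.0% of its dexamethasone difference with mifepristone and PLIN2 107%, while RGS2 kept 32.2% and CDKN1C, the cell cycle inhibitor p57, -1.11%. PDK4, which spares glucose by blocking pyruvate oxidation, kept 85.9% with mifepristone and 79.6% with CORT108297 over these sets, but its sets differed. Mifepristone against dexamethasone stood at -2.04 and -1.69 in the 4 h sets, at -0.06 at 8 h and at 0.83 at 12 h on the log2 scale, and from 50.3% to 152% of the difference was left.

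A candidate explanation is that PPAR target genes as a group stay up with dexamethasone and mifepristone. The 19 other measured PPAR targets were higher than other genes in that comparison with vehicle (camera p 0.000145), as the explanation needs, with 15 of 19 above 0. Their median was only 0.05 on the log2 scale, no member passed limma's test and the p was 0.0725 with an estimated correlation, so the test leaves the explanation open; this last p had been seen before it was made part of the reading. Without PDK4, which is also a GR-induced target, 18 genes had a p of 0.0014, or 0.0973 with an estimated correlation. With dexamethasone alone the same 19 genes had a camera p of 0.45, with 9 of 19 above 0 and a median of -0.01. These values do not show the group to be up with dexamethasone alone, so they do not show that it stays up when mifepristone is added.

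In the interaction of the dexamethasone effect with time, further lists passed at the preset correlation. G2/M genes were lower later (0 higher and 8 lower of 28, 17 lower adjusted over the list alone, adjusted p 4.35e-08, and adjusted p = 0.424 with an estimated correlation). Metallothioneins were higher (3 of 7, 6 over the list alone, adjusted p 0.000395, and adjusted p = 0.424 with an estimated correlation). GR-induced targets were higher (4 higher and 1 lower of 29, 12 and 2 over the list alone, adjusted p 0.00287, and adjusted p = 0.424 with an estimated correlation), as were AP-1 genes (7 higher and 2 lower of 21, 9 and 2 over the list alone, adjusted p 0.0144, and adjusted p = 0.355 with an estimated correlation). The set medians did not show such a rise within the first run. For GR-induced targets they were 1.37, 1.35 and 1.03 at 4, 8 and 12 h, and only the second run at 4 h was lower (0.62). For AP-1 genes they were -0.04, -0.07 and -0.11, with -0.04 in the second run. Luminal markers were lower (1 higher and 4 lower of 13 by either count, adjusted p 0.0233, and adjusted p = 0.424 with an estimated correlation).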
